A study of Mus musculus with 77 samples.

How the data were processed

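The series holds 77 libraries from mouse embryonic stem (ES) cells of the R1 line and from the same cells during neural differentiation, 65 by RNA-seq of polyadenylated RNA and 12 by ATAC-seq, an assay of open chromatin. Per the labels' protocols, ES cells were grown on feeder cells, passaged without them, and moved to N2B27 medium, which gives neural progenitor cells (NPCs) by day 4 and, after replating, neurons by day 8. Groups were taken from the sample titles, because the genotype field of the labels reads wild type for the mutant lines as well. Both hairpins, gapmers or clonal lines of 1 target formed 1 arm, so that the spread within an arm holds the difference between them.

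Per the submitters' processing notes, the authors quantified each RNA-seq library with RSEM against RefSeq transcripts on genome build mm9. The aligner and the versions are not given in the sources used here. Per the file headers, the deposited RNA-seq files hold RSEM expected counts, TPM and FPKM, with gene lengths and effective lengths in bases. The ATAC-seq protocol text in the labels follows Buenrostro et al. and describes dorsal root ganglia, while the titles name NPCs of day 2. The libraries were grouped by their titles, and this conflict was not resolved. Each deposited ATAC-seq file lists the peaks of 1 library with, per the file headers, a score, the fold enrichment over background (a ratio) and the -log10 p and -log10 q values. The ATAC files give no read counts, so the depth of those libraries is unknown and the number of peaks stands beside each value.

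Row IDs were matched to gene names by gene ID, and otherwise by transcript accession. Of the 24912 rows in 59 of the RNA-seq files, 21174 matched by gene ID, 2437 by transcript, 1073 were copies of transcripts at several loci, 156 held several gene IDs and 72 had no match. The 6 files of the day 2 shRNA experiment have 24989 rows, of which 23447 matched by gene ID and 20 had no match. Rows without a match held up to 5.14% of counts, in the gapmer experiment. Rows with several gene IDs are printed with their IDs and may sum several genes. No mm9 gene coordinates were held, so ATAC peaks were not assigned to genes. The lncRNA Reno has no row under that name. The row 2810410L24Rik, the annotated lncRNA next to Bahcc1, was read as Reno. The row A830082K12Rik was read as the lncRNA named lnc-Nr2f1 in the labels, and no row was found for Cox10as1. Neither reading is stated in the labels.

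Expected counts were rounded and tested per experiment with edgeR 4.0.16 (TMM scaling, filterByExpr by arm, glmQLFit and glmQLFTest) in R 4.3.3, in 15 contrasts. All tests of genes and lists are two-sided, and a gene was called at an adjusted p (Benjamini-Hochberg over the genes of a contrast) under 0.05. The standard error (SE) of a log2 difference is its size divided by the square root of F. Levels are CPM (counts scaled by library size) with TMM scaling, given as mean ± SD. In 20 gene lists (pluripotency, formative and primed epiblast, neural progenitor, proneural, neuronal, glial, mesoderm, endoderm, surface ectoderm, fibroblast, cell cycle, p53 targets, interferon response, integrated stress, Hox and Cdx, Notch, Wnt targets, BMP and TGF-beta, imprinted and Y-linked), no gene stood in more than 1 list. Each list was tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 20 lists. Because that correlation is low, the adjusted p of camera with an estimated correlation stands beside each call, and fry was run as well. fry tests whether a list moves one way and compares it with no other genes.

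The 3 libraries of ES cells, NPCs and neurons have no replicates. They were compared by log2 ratios of CPM with a pseudocount of 1, among genes of at least 50 CPM in ES cells or neurons. The median ratio of a list was set against 10000 random lists of equal size, each gene drawn from the 100 genes nearest in expression. ATAC regions were the merged peaks of the 8 libraries compared. A region was lost or gained when it held a peak in at least 3 of the 4 libraries of one genotype and in 0 of the 4 of the other. Peak numbers were compared by two-sided exact permutation of the 8 libraries, and shared positions by the Jaccard index of pairs of libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

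The comparisons, lists, tests, alternatives and the rule for naming genes were fixed before the data were examined. Named genes are the targeted genes with up to 3 neighbours of Bahcc1 on each side. Added to them, per contrast, are called genes with a mean log2 CPM of at least 2 and no overlap between the arms, up to 6 with the largest rise and 6 with the largest fall. Each list gives up to 4 called members, or its 2 most expressed where none was called. Members of the neuronal, proneural, progenitor and pluripotency lists may be followed across contrasts. Not all genes this rule names are reported here. Up to 5 lost and 5 gained ATAC regions are named by fold enrichment. Alternatives were RLE scaling, no filter and a stricter filter on low counts, DESeq2 1.42.0, the replicate number as a block, each line or hairpin with its own coefficient or alone, counts summed per line, and leaving out each library in turn. For lists, the estimated correlation and fry were added. For the stages they were TPM, a pseudocount of 0.1 and a minimum of 10 CPM, and for ATAC a stricter q value, equal numbers of strongest peaks, a 50% overlap and 4 libraries against 0. Leaving out libraries of low complexity, and leaving out each library for the ATAC peak numbers, were added after the data were seen.

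The pipeline was tested on simulated data with the depth and spread of each experiment, 100 genes changed 2-fold and 100 changed 4-fold. It recovered 53% and 89% on day 8, 55% and 96% on day 4, 9% and 79% for the day 2 shRNAs, 89% and 100% for the gapmers, 87% and 98% for the day 2 mutants, and 3% and 61% in the rescue. False calls numbered 2 to 13. None of the 43 pairs of libraries within a group were copies of each other (chi-square per degree of freedom 7.39 to 122). Libraries with the same replicate number were checked for pairing after removal of the group means. Only the day 2 mutants met the rule, which asks for at least 3 shared numbers and a correlation above 0.1 in all pairs, and did so in 15 of 15 pairs (r 0.105 to 0.668). The value with the replicate number as a block is given there beside a result whose call it changed or whose count it moved by over 1.5 times. Nothing in the labels says that replicates are separate cultures, so p-values measure only the spread between samples.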

Results

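RNA was sequenced from 65 libraries and open chromatin was mapped in 12, all from mouse R1 ES cells or cells differentiating from them toward neurons. A first set followed the differentiation itself with 1 library each of ES cells, NPCs on day 4 and neurons on day 8 (24.5 to 47.0 M counts, M for mega). On day 8, short hairpin RNAs (shRNAs) against the lncRNAs Reno, lnc-Nr2f1 and Cox10as1 (4 libraries each, from 2 hairpins) were compared with a non-targeting (NT) hairpin (3 libraries, 16.7 to 35.3 M counts). On day 4, wild-type (WT) cells, Reno m/m cells and Bahcc1 m/m cells had 4 libraries each from 2 clonal lines (7.72 to 14.3 M counts). Reno m/m lines lack the promoter and first exon of Reno, and Bahcc1 m/m lines carry short deletions that include the start codon of Bahcc1. Day 2 cells were studied with shRNAs against Reno or Bahcc1 and the NT hairpin (2 libraries each, 9.22 to 28.2 M counts). Antisense gapmers were used against Reno (5 libraries) with scrambled gapmers (2 libraries, 5.23 to 35.2 M counts). Reno m/m (6) and WT (5) libraries were also made on day 2 (10.1 to 18.5 M counts). The last set, described as a rescue, held WT2 cells and cells titled Renonm/m2, read here as Reno m/m2, with and without doxycycline (Dox), with 3 libraries per group and 2 for Reno m/m2 without Dox (3.04 to 9.62 M counts). ATAC-seq on day 2 covered WT, Reno m/m and Bahcc1 m/m cells, with 4 libraries each.

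The ES cell, NPC and neuron libraries show how far the cells moved toward neurons. Regulators of neurogenesis and markers of neurons were higher in neurons than in ES cells. All 29 measured proneural genes and 36 of 42 neuronal genes were higher (median log2 ratios 3.81 and 2.52), as were 27 of 30 neural progenitor genes (3.72). Tubb3, the neuronal beta tubulin, stood at 122 CPM in ES cells, 99.0 in NPCs and 682 in neurons. The neurofilament gene Nefm stood at 4.46, 10.9 and 541 CPM, and the radial glia gene Fabp7 at 0.255, 9.89 and 314 CPM. Dbx1, Dcx and Pou3f2, which act in neural progenitors and young neurons, had no counts in ES cells and reached 162, 108 and 98.4 CPM in neurons. All 28 pluripotency genes were lower in neurons (median -2.57). Pou5f1, the ES cell factor Oct4, went from 1110 to 724 and then 226 CPM. Formative genes were higher in NPCs (median 1.45 over ES cells) and lower in neurons (-0.54), with the DNA methyltransferase gene Dnmt3b at 499, 1712 and 246 CPM.

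Fibroblast genes, listed because the ES cells had been kept on feeder cells, were lower in neurons for 20 of 21 members (median -2.75). Of the listed genes, S100a4 stood at 86.9 CPM in ES cells and had no counts later. It was among the 5 largest falls, with Tnc (708, 1.04 and 2.90 CPM) and Bgn (301, 0.839 and 1.92 CPM), matrix genes outside the list. Medians of other lists in neurons over ES cells were 3.11 for endoderm, which holds basement membrane genes such as Col4a1 (130, 234 and 2189 CPM), 1.49 for glia, 1.27 for Notch, 1.19 for Hox and Cdx, 0.70 for imprinted genes, 0.54 for Wnt targets and 0.42 for the stress response. They were -1.85 for interferon response, -0.86 for mesoderm, -0.46 for BMP and TGF-beta and -0.41 for Y-linked genes. Cell cycle (-0.00, or 0.09 with TPM in place of CPM), surface ectoderm (0.01) and p53 targets (0.05) lay near 0. Of 10000 random lists, none had a median as high as those of the progenitor, proneural, neuronal and endoderm lists or as low as those of the pluripotency, fibroblast and interferon lists. Bahcc1, which codes for a chromatin protein, stood at 42.7, 124 and 152 CPM, and the row read as Reno, 2810410L24Rik, at 0.255, 0.457 and 3.35 CPM (12, 18 and 82 counts). Among 5215 genes, 870 were at least 2-fold higher in neurons and 458 at least 2-fold lower. With 1 library per stage, these differences have no check against replicates.

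**Figure D1:**
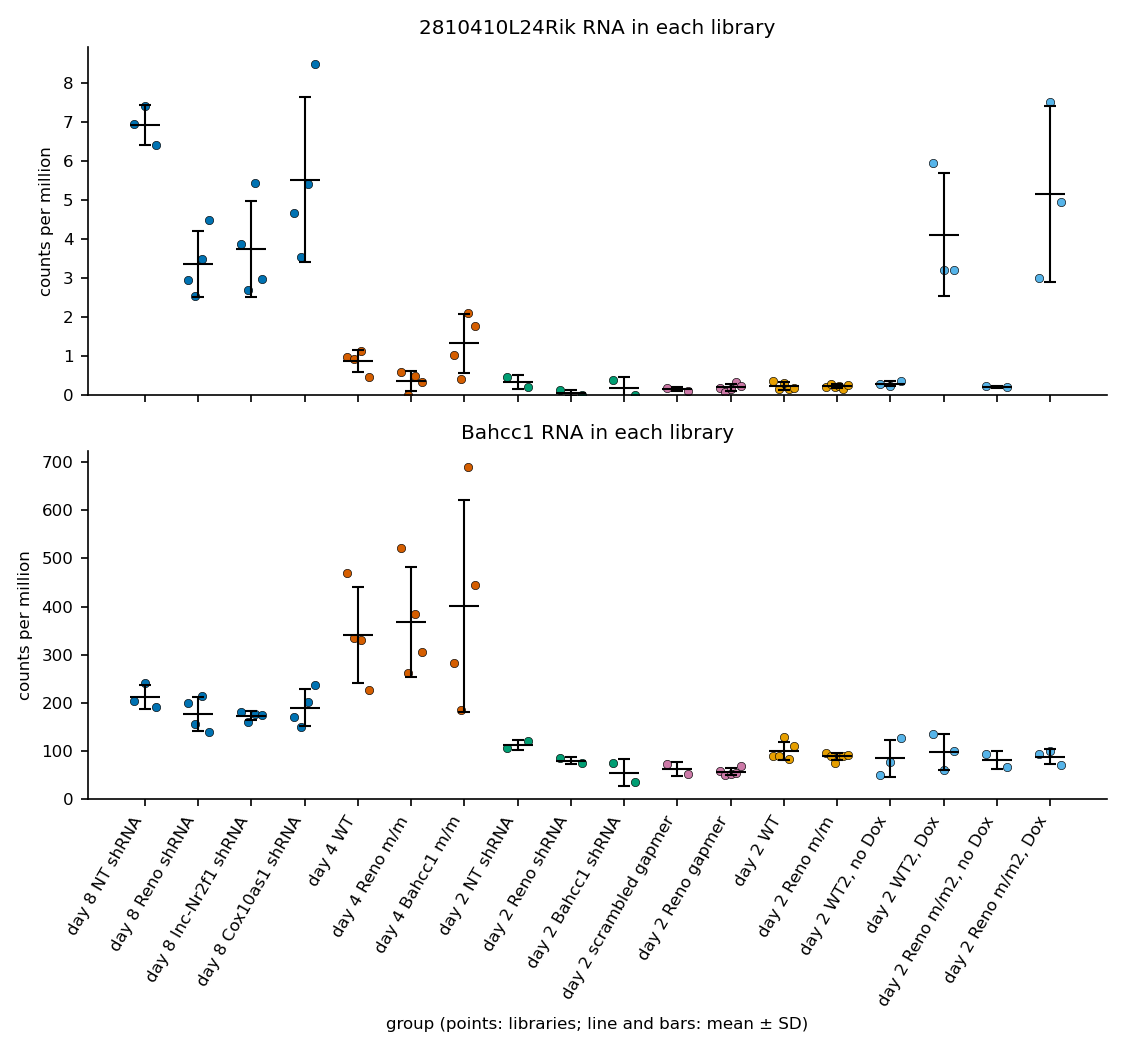
Levels of 2810410L24Rik (read as Reno) and Bahcc1 in CPM in each library, by arm, with points for libraries and lines for the mean ± SD.

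The day 8 shRNAs ask what each lncRNA does for the cells that become neurons. With the Reno shRNAs, 2810410L24Rik stood at 3.36 ± 0.844 CPM (SD, n = 4) against 6.92 ± 0.507 CPM with the NT hairpin (n = 3), a log2 difference of -1.04 ± 0.31 (SE) that did not pass the test (edgeR, adjusted p = 0.240). Bahcc1 stood at 177 ± 35.1 CPM against 212 ± 25.3 CPM (-0.26 ± 0.17, adjusted p = 0.494). The neuronal list was lower, with 1 of its 42 members above 0 and a median of -0.78 (camera, adjusted p = 1.91e-14), and the proneural list with 4 of 31 members above 0 and a median of -0.42 (adjusted p = 0.000266). The cell cycle list was higher, with all 26 members above 0 and a median of 0.48 (adjusted p = 2.88e-12). With an estimated correlation, none of these calls held (adjusted p = 0.580, 0.690 and 0.580). No single member passed over all genes. Adjusted over the list alone, 2 proneural genes were lower and 5 cell cycle genes higher. Tubb3 stood at 1021 ± 157 CPM against 1507 ± 519, Dpysl3, which acts in axon growth, at 870 ± 130 against 1525 ± 282, and Nhlh2, a proneural type factor, at 208 CPM against 347 (adjusted p of 0.331 or more). Top2a, which untangles DNA in dividing cells, stood at 1473 ± 242 CPM against 844 ± 293 and the p53 target Ccng1 at 802 ± 126 against 468 ± 132 (adjusted p = 0.240 for both).

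Interferon response (median 0.94, adjusted p = 0.00264) and Y-linked genes (0.77, adjusted p = 0.00198) were also higher with the Reno shRNAs, but not with an estimated correlation (adjusted p = 0.580 and 0.146). Pluripotency (0.96), p53 target (0.22) and endoderm (-0.20) lists also passed (adjusted p = 0.0438, 0.0348 and 0.0438, and 0.945, 0.858 and 0.869 with an estimated correlation). The pluripotency gene Dppa5a varied widely, at 114 ± 135 CPM against 38.2 ± 26.1 CPM. RLE scaling ended the pluripotency call (adjusted p = 0.0624), and leaving out NT replicate 1, Reno shRNA1 replicate 2 or Reno shRNA2 replicate 2 ended it and the p53 call (adjusted p up to 0.878 and 0.204). The endoderm call ended without NT replicate 2 or 3 or without either replicate of Reno shRNA2 (adjusted p up to 0.556, median up to 0.08). Without Reno shRNA1 replicate 2 the endoderm, proneural and interferon medians were -1.23, -0.28 and 0.60, and without NT replicate 1, 2 or 3 those of endoderm, cell cycle and pluripotency genes were -0.42, 0.31 and 1.49. Of 14923 genes, edgeR called 0 with the Reno shRNAs, while 2104 had an unadjusted p under 0.05 and DESeq2 called 216.

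With the lnc-Nr2f1 shRNAs, A830082K12Rik, read as lnc-Nr2f1, stood at 6.48 ± 3.20 CPM (n = 4) against 14.9 ± 2.55 CPM (n = 3; -1.20 ± 0.41, adjusted p = 0.217), and Nr2f1, a nuclear receptor of the developing brain, at 71.1 ± 33.9 against 120 ± 8.67 CPM (-0.76 ± 0.38, adjusted p = 0.287). 2810410L24Rik was at 3.74 ± 1.23 CPM (-0.89, adjusted p = 0.219). Neuronal (median -0.91, adjusted p = 1.09e-18) and proneural genes (-0.63, adjusted p = 6.41e-07) were lower by camera, and cell cycle genes higher (0.53, adjusted p = 2.95e-12), but each had an adjusted p of 0.624 with an estimated correlation. Adjusted over the list alone, 11 neuronal genes were lower and 19 cell cycle genes higher, against 0 over all genes. Higher lists were also pluripotency (0.76), mesoderm (1.37), p53 targets (0.48) and interferon response (0.89), and neural progenitor genes were lower (-0.23), with adjusted p of 0.00102 to 0.0407, and 0.628 to 0.661 with an estimated correlation. The pluripotency call ended without NT replicate 1 (adjusted p = 0.120). The progenitor and mesoderm calls ended without NT replicate 1 or lnc-Nr2f1 shRNA2 replicate 2, the former also without NT replicate 3 and the latter without NT replicate 2 or lnc-Nr2f1 shRNA1 replicate 2 (adjusted p up to 0.120 and 0.113). The pluripotency median was 1.17 without NT replicate 3 and the progenitor median -0.40 without lnc-Nr2f1 shRNA2 replicate 1. edgeR called 0 genes, 2810 had an unadjusted p under 0.05 and DESeq2 called 136.

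With the Cox10as1 shRNAs, the target itself could not be measured, and Cox10, the gene in its name and an assembly factor of the respiratory chain, stood at 50 ± 3.57 CPM (n = 4) against 42.5 ± 11.7 (n = 3; 0.24 ± 0.21, adjusted p = 0.935). Neuronal genes were again lower by camera (median -0.43, adjusted p = 5.84e-11), as were proneural (-0.23) and Hox and Cdx genes (-0.69). Fibroblast genes were higher in all 20 measured members (median 1.05, adjusted p = 8.5e-07). Pluripotency (0.87), interferon response (0.88), p53 target (0.36), cell cycle (0.26) and Y-linked genes (0.58) were higher too, all with adjusted p of 0.00208 or less. With an estimated correlation, none of these 9 lists passed (adjusted p = 0.194 to 0.600). Over the list alone, 2 p53 targets and 1 interferon gene were higher and 1 p53 target lower. Leaving out NT replicate 1 or Cox10as1 shRNA1 replicate 2 ended the pluripotency call (adjusted p up to 0.354), the latter also the proneural call (0.103), and leaving out NT replicate 2 the Y-linked call (0.0977). Without NT replicate 1 the proneural median was -0.14, without NT replicate 2 the fibroblast and cell cycle medians 0.64 and 0.14, and without NT replicate 3 the pluripotency, proneural and cell cycle medians 1.31, -0.34 and 0.41. Without shRNA1 replicate 1 the neuronal, fibroblast and cell cycle medians were -0.29, 0.63 and 0.17, without its replicate 2 the neuronal, cell cycle and p53 medians -0.28, 0.16 and 0.18, and without shRNA2 replicate 2 the neuronal, proneural, cell cycle and Hox medians -0.70, -0.37, 0.41 and -1.37. edgeR called 0 genes, 582 had an unadjusted p under 0.05 and DESeq2 called 4.

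The 3 targets share their controls, which alone makes their differences correlate. Across genes, which are not independent replicates, log2 differences correlated at r = 0.724 for Reno and lnc-Nr2f1, 0.777 for Reno and Cox10as1 and 0.664 for lnc-Nr2f1 and Cox10as1. In simulated data without any change they correlated at 0.587, 0.587 and 0.578. Covariances were 0.241, 0.219 and 0.206, against 0.128, 0.127 and 0.127 in simulation. Groups without overlap were found for 16.1% of genes with the Reno shRNAs, 15.0% with lnc-Nr2f1 and 2.83% with Cox10as1, where chance gives 5.71%.

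On day 4, the mutant lines ask what the deletions at Reno and Bahcc1 change in NPCs. In Bahcc1 m/m cells, Bahcc1 RNA stood at 401 ± 220 CPM (n = 4) against 340 ± 100 CPM in WT (n = 4; 0.23, adjusted p = 0.782), for a deletion that removes the start codon and not the gene, and protein was not measured. Of 13463 genes, edgeR called 314 in these cells, 186 higher and 128 lower, 192 of them at least 2-fold. Genes of the formative state, which ES cells pass through early in differentiation, were higher. All 12 were above 0 (median 1.03, camera adjusted p = 4.07e-11, and 0.0711 with an estimated correlation). Over all genes 4 rose and 8 did not pass, and 9 rose adjusted over the list alone. Dnmt3b rose from 307 ± 144 to 1141 ± 478 CPM and Fgf5, a growth factor of the epiblast, from 5.90 ± 2.53 to 27.9 ± 11.3 CPM. In the pluripotency list 4 of 28 members rose, 6 over the list alone (median 0.37, adjusted p = 0.00141, and 0.539 with an estimated correlation). They were Utf1 (1136 ± 471 against 286 ± 47.2 CPM), Fgf4 (69.1 ± 18 against 13.8 ± 7.69), L1td1 and Dppa2.

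Epithelial genes were lower in the same cells. Of 17 surface ectoderm genes 4 fell, and over the list alone 7 fell and 2 rose (median -0.86, adjusted p = 7.34e-06, and 0.151 with an estimated correlation). The keratin genes Krt8 (63.0 ± 12.6 against 212 ± 45 CPM), Krt18 (72.3 ± 15.0 against 193 ± 13.8) and Krt19 (12.9 ± 3.65 against 42.8 ± 6.66) were among them. Outside the list Krt7 fell as well (-2.86 ± 0.47, adjusted p = 0.00708), as did Wnt6 (-3.47 ± 0.60). Of 11 BMP and TGF-beta genes 3 fell, Id3, Tgfbi and Nog, 4 over the list alone (median -0.53, adjusted p = 0.00184, and 0.0863 with an estimated correlation). Endoderm (2 of 16 fell, Col4a2 and Dab2, 3 over the list alone, median -0.83), Hox and Cdx (0 of 14, 4 over the list alone, -0.66) and fibroblast genes (1 of 19, Col5a1, 5 over the list alone, -0.38) were lower by camera, with adjusted p of 0.005 or less, and 0.350, 0.0766 and 0.350 with an estimated correlation. WT1 replicate 2 had a higher mean log2(CPM + 1) of fibroblast genes than the other WT libraries (4.69, next 4.09), and without it the fibroblast call ended (adjusted p = 0.124).

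Imprinted genes, expressed from 1 parental copy, fell in Bahcc1 m/m cells, with 6 of 16 called over all genes and over the list alone (median -0.53, adjusted p = 1.28e-08, and 0.0022 with an estimated correlation). H19 fell from 194 ± 97.1 to 5.02 ± 1.64 CPM, a log2 change of -5.28 ± 0.51 (adjusted p = 0.000302). Nnat fell from 786 ± 357 to 160 ± 22.6 CPM, Plagl1 from 141 ± 48.8 to 40.8 ± 9.02 and Dlk1 from 107 ± 19.9 to 42.3 ± 8.51. Of 17 targets of p53, the tumour suppressor that answers DNA damage, 3 rose and 4 over the list alone (median 0.41, adjusted p = 1.68e-05, and 0.0711 with an estimated correlation). Aen stood at 132 ± 12.6 against 60.8 ± 10.7 CPM and Bax at 126 ± 13.1 against 70.8 ± 17.8, and both act in cell death. The stress response list (0.27) and the proneural list (-0.35) passed by camera (adjusted p = 0.0177 and 0.0476, and 0.359 and 0.702 with an estimated correlation). Of neural genes, Zic1 fell (38.6 ± 9.16 against 92.4 ± 30.8 CPM), while Gbx2 (110 ± 25.2 against 52.1 ± 6.77) and the neuronal gene Gng3 (195 ± 51.1 against 73.7 ± 18.8) rose. The largest rises were of Slc35d3 (4.33 ± 0.77), Anks1b (3.16 ± 0.61), Foxd3, a factor of pluripotent and neural crest cells (3.14 ± 0.73), and Calcr (3.08 ± 0.48). Cass4 (2.77), Celf4 (0.99), Eda2r (0.91) and Zic2 (0.88) rose and Gprc5a (-2.44), Hand1 (-2.19), Msx2 (-1.74) and Bmp4 (-1.45) fell as well.

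The count of 314 in Bahcc1 m/m cells rests on several libraries. It was 82 without WT1 replicate 1, 69 without WT1 replicate 2, 190 without WT2 replicate 1, 208 without WT2 replicate 2, 127 without Bahcc1 m/m1 replicate 1 and 79 without Bahcc1 m/m2 replicate 1. Bahcc1 m/m2 replicate 2 had 5.56% of moderately expressed genes at 0 counts, where libraries without such losses had at most 0.697%, and 514 genes were called without it and a like Reno m/m1 library. Bahcc1 m/m1 alone against WT gave 5 genes and m/m2 alone 133. Lines with own coefficients gave 182, DESeq2 828 and a replicate block over 314. The pluripotency call ended without Bahcc1 m/m1 replicate 1 (adjusted p = 0.0665) and the stress call without WT2 replicate 2 or Bahcc1 m/m1 replicate 2 (up to 0.108). The proneural call ended with RLE scaling, without the low-complexity libraries, and without WT1 replicate 1, either replicate of Bahcc1 m/m1 or Bahcc1 m/m2 replicate 2 (up to 0.566). Without Bahcc1 m/m2 replicate 1 the proneural and p53 medians were -0.62 and 0.23, and without Bahcc1 m/m1 replicate 2 the endoderm and BMP medians -0.55 and -0.34.

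In Reno m/m cells on day 4, 2810410L24Rik stood at 0.358 ± 0.260 CPM (n = 4, 15 counts) against 0.874 ± 0.286 CPM in WT (n = 4, 43 counts), a log2 difference of -1.25 ± 0.76 (adjusted p = 0.769). In Bahcc1 m/m cells it was at 1.33 ± 0.757 CPM (0.59, adjusted p = 0.726). Bahcc1 stood at 368 ± 114 CPM in Reno m/m cells (0.11, adjusted p = 0.973). edgeR called 11 genes, 9 higher and 2 lower. Xist, the RNA that silences an X chromosome, rose from 0.765 ± 0.368 to 13.1 ± 3.06 CPM (4.08 ± 0.40, adjusted p = 0.000429). The carbonyl reductase gene Cbr3 rose from 2.86 ± 0.954 to 13 ± 4.37 CPM, Eng, a receptor of TGF-beta ligands, from 29.5 ± 3.13 to 87.7 ± 23.8, Pde2a from 4.20 ± 0.664 to 12.4 ± 1.91, Zfp365 from 8.22 ± 1.97 to 25.8 ± 8.64 and Ttn from 7.09 ± 2.24 to 29.5 ± 18. The imprinted genes Peg13 (2.26 ± 0.583 against 8.87 ± 1.94 CPM, -1.98 ± 0.30, adjusted p = 0.0183) and Dlk1 (42.5 ± 7.87 against 107 ± 19.9, -1.33 ± 0.20, adjusted p = 0.0148) fell.

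Targets of p53 were higher in Reno m/m cells, with 15 of 17 above 0 and a median of 0.72 (camera, adjusted p = 4.73e-17, and 0.00402 with an estimated correlation). None passed over all genes, and 10 were higher adjusted over the list alone. Ccng1 stood at 447 ± 194 against 191 ± 64.5 CPM (1.22 ± 0.31, adjusted p = 0.214) and Zmat3 at 315 ± 61.8 against 185 ± 7.22 CPM (0.77 ± 0.18, adjusted p = 0.177). Imprinted genes were lower (median -0.43, adjusted p = 0.000351, and 0.0260 with an estimated correlation), with 1 of 16 called and 4 over the list alone. Formative (0.78, all 12 above 0) and pluripotency genes (0.59, 25 of 28 above 0) were higher by camera (adjusted p = 2.23e-06 and 1.04e-06, and 0.193 and 0.393 with an estimated correlation), with 0 called over all genes, and 4 and 5 over the list alone. Lower by camera were proneural (median -0.38), fibroblast (-0.60), surface ectoderm (-0.42), Hox and Cdx (-0.26), Y-linked (-0.64) and endoderm genes (-0.24), with adjusted p of 6.54e-05 to 0.0278, and 0.193 to 0.452 with an estimated correlation. Over the list alone 4 surface ectoderm, 3 Hox and 2 fibroblast genes were lower. The Y-linked median depends on 1 library, since Reno m/m1 replicate 1 had a mean log2(CPM + 1) of 1.01 and the other 3 Reno m/m libraries were at 0. It was -7.22 without that library, a fitted value against 0 counts and no measure of size, and -0.37 to -0.17 without WT1 replicate 2 or any 1 of the other Reno m/m libraries. The stress list was higher (0.17, adjusted p = 0.0212, and 0.393 with an estimated correlation).

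The 11 calls in Reno m/m cells fell to 2 without WT1 replicate 1, 1 without WT1 replicate 2, 7 without Reno m/m1 replicate 1 and 4 without Reno m/m2 replicate 2, and either line alone against WT gave 1. DESeq2 called 113 and counts summed per line gave 40. Without Reno m/m2 replicate 1 the pluripotency call ended (adjusted p = 0.0976). The proneural, endoderm and stress calls ended without Reno m/m1 replicate 2, in which 1.72% of moderately expressed genes were at 0 counts and without both low-complexity libraries (over these and each library left out, adjusted p up to 0.111, 0.611 and 0.174 and endoderm median up to 0.05). WT1 replicate 1 also ended the proneural and endoderm calls when left out, WT1 replicate 2, Reno m/m1 replicate 1 and Reno m/m2 replicate 2 the endoderm call, and WT2 replicate 2 and Reno m/m2 replicate 2 the stress call. The fibroblast median was -0.26 without WT1 replicate 2, the Hox and proneural medians -0.54 and -0.64 without WT2 replicate 2 and -0.61 and -0.60 without Reno m/m1 replicate 1, and the imprinted median -0.28 without both low-complexity libraries. Without Reno m/m2 replicate 1 the proneural, endoderm and stress medians were -0.72, -0.60 and 0.30, and without its replicate 2 the proneural median was -0.21. Genes whose groups did not overlap made up 6.10% in Reno m/m cells and 13% in Bahcc1 m/m cells, where chance gives 2.86%.

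Both mutants were set against each other to ask whether both deletions do the same. Of the 11 genes called in Reno m/m cells, all 9 higher and 1 of 2 lower were called the same way in Bahcc1 m/m cells, where independent sets would share 0.124 and 0.0190. Both contrasts use the same WT libraries. Simulated data with shared controls and no change gave 0.05 and 0 shared calls, but hold too few calls to test the overlap. The 6 ways to divide the WT libraries 2 and 2 between the mutants gave 0.167 and 0 on average, with 2 controls each. The shared genes with all 4 WT libraries were Xist (2.41 in Bahcc1 m/m, adjusted p = 0.00741), Cbr3 (2.58, adjusted p = 0.00089), Eng (1.62, adjusted p = 0.00268), Ak1, Slc19a2, Pde2a, Slc39a14, Zfp365, Ttn and Dlk1. Log2 differences correlated at r = 0.668 across genes, against 0.495 (0.479 to 0.508) in simulated data with the same shared controls. Their covariance was 0.171 against 0.0771, and 0.129 (r = 0.424) when the WT libraries were split so that no library served both. Tested directly, 1 gene differed. Peg13 was lower in Reno m/m (2.26 ± 0.583 CPM) than in Bahcc1 m/m cells (10.4 ± 2.53 CPM, -2.21 ± 0.31, adjusted p = 0.0341), while 711 genes had an unadjusted p under 0.05 and DESeq2 called 13. Leaving out Reno m/m1 replicate 1 gave 6 genes and replicate 2 gave 3, and leaving out any 1 of the other 6 libraries gave 0. Groups without overlap made up 2.82% of genes, where chance gives 2.86%.

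Between the mutants, imprinted genes were higher in Reno m/m than in Bahcc1 m/m cells, with 12 of 16 above 0 and 4 over the list alone (median 0.38, adjusted p = 5.52e-06, and 0.00747 with an estimated correlation). Formative genes were lower in Reno m/m (median -0.51, adjusted p = 1.39e-05, and 0.235 with an estimated correlation), as were Y-linked genes (-1.84, adjusted p = 2.32e-05, and 0.161), with a fitted median of -8.65 without Reno m/m1 replicate 1, when all Reno m/m libraries were at 0. Endoderm (0.43), surface ectoderm (0.51), p53 target (0.23) and BMP and TGF-beta genes (0.39) were higher (adjusted p = 0.0116 to 0.0420, and 0.213 to 0.565 with an estimated correlation). Each of the last 4 calls ended without Bahcc1 m/m1 replicate 2. The endoderm and surface ectoderm calls also ended without Reno m/m1 replicate 1 or Reno m/m2 replicate 1, the endoderm call without Bahcc1 m/m1 replicate 1, and the p53 call without either Reno m/m1 library or both low-complexity libraries (adjusted p up to 0.7, 0.181, 0.151 and 0.110 for the 4 lists). The endoderm median was 0.27 without Bahcc1 m/m2 replicate 2 and the BMP median 0.25 without Reno m/m2 replicate 1.

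**Figure D2:**
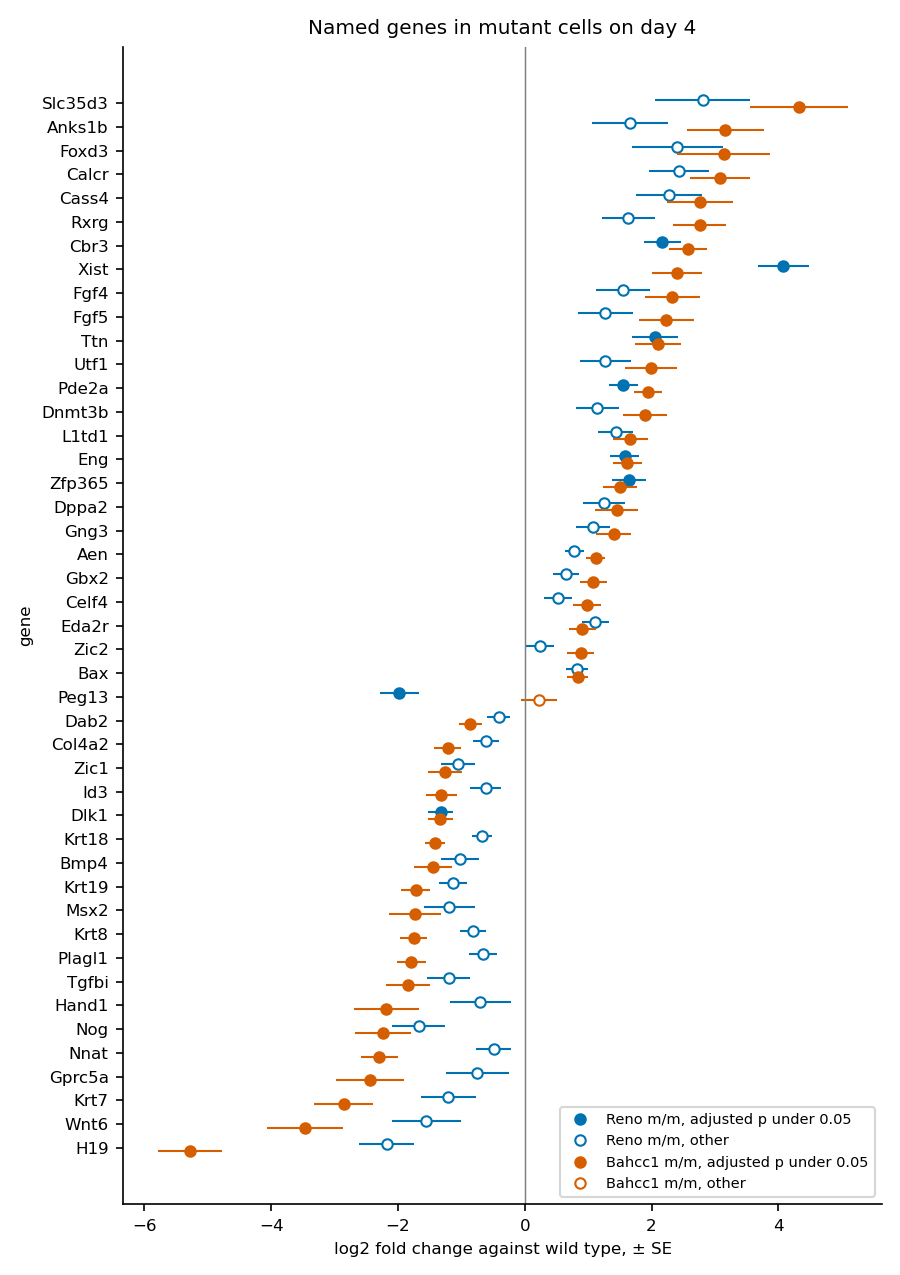
Log2 differences from WT on day 4 in Reno m/m and Bahcc1 m/m cells for named genes, with bars for the SE (n = 4 libraries per genotype) and filled points for an adjusted p under 0.05. Xist, Cbr3, Eng and Dlk1 are called in both mutants, H19 (-5.28) in Bahcc1 m/m and Peg13 (-1.98) in Reno m/m.

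Reno m/m cells were also profiled on day 2, early in differentiation, to ask what the deletion does before NPCs form. 2810410L24Rik was too low to test, at 0.225 ± 0.0485 CPM (n = 6) against 0.238 ± 0.0957 CPM in WT (n = 5). Bahcc1 stood at 88.7 ± 7.11 against 101 ± 19 CPM (-0.18, adjusted p = 0.618) and its neighbour Actg1, a cytoplasmic actin, at 5702 ± 625 against 8165 ± 1056 (-0.52, adjusted p = 0.114, or 0.0482 with the replicate number as a block and 0.00297 by DESeq2). Of 13481 genes edgeR called 12, of which 8 rose and 4 fell. Ooep, a gene of eggs and early embryos, rose from 36.0 ± 4.26 to 69.7 ± 13.8 CPM (0.95 ± 0.15, adjusted p = 0.0223) and the helicase gene Dhx16 from 96.9 ± 16.7 to 184 ± 38.0 (0.93 ± 0.16, adjusted p = 0.0407). D630023F18Rik (1.31 ± 0.20), Phf11d (1.2), Cyp4f16 (1.18) and Zfp750 (1.16) rose too. The insulin receptor substrate gene Irs2 fell from 54.6 ± 10.1 to 29.2 ± 3.65 CPM (-0.91 ± 0.14, adjusted p = 0.0191), Ahnak from 72.9 ± 14.8 to 32.8 ± 10.7 and Sh3rf1 from 28.6 ± 5.74 to 15.5 ± 1.45. Peg13, which lies below the level asked for in the naming rule and is named because it was called on day 4, fell by 2.55 (adjusted p = 0.0191).

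Targets of p53 were higher on day 2 as well, with 16 of 17 above 0, 0 called over all genes and 9 over the list alone (median 0.36, adjusted p = 1.15e-08, and 0.0250 with an estimated correlation). Zmat3 stood at 231 ± 12.6 against 180 ± 30.4 CPM and Ccng1 at 265 against 197 CPM. Pluripotency genes were higher (median 0.30, 7 of 28 over the list alone, adjusted p = 1.57e-05, and 0.224 with an estimated correlation), with Dppa5a at 1149 ± 300 against 611 ± 67.1 CPM (adjusted p = 0.0678, or 0.0233 with the replicate number as a block and 0.000398 by DESeq2). All 10 BMP and TGF-beta genes were below 0 (median -0.32, adjusted p = 7.48e-06, and 0.0835 with an estimated correlation), 4 of them lower over the list alone. Fibroblast (-0.60), endoderm (-0.43), imprinted (-0.41), surface ectoderm (-0.35), Notch (-0.35) and progenitor genes (-0.15) were lower, and cell cycle genes higher (0.10), with adjusted p of 7.23e-06 to 0.0288, and 0.199 to 0.423 with an estimated correlation. Over the list alone 4 imprinted and 2 endoderm genes were lower. The progenitor call ended without WT1 replicate 3 or Reno m/m1 replicate 1 or 3 (adjusted p up to 0.209, median up to 0.00), and the cell cycle call without WT2 replicate 1 or 3, WT1 replicate 3, Reno m/m1 replicate 3 or Reno m/m2 replicate 2 (up to 0.190). Without WT2 replicate 1 the progenitor, fibroblast and imprinted medians were -0.24, -0.32 and -0.25, without WT1 replicate 1 the imprinted median -0.27, and without Reno m/m2 replicate 2 the progenitor median -0.37.

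With the replicate number as a block, 108 genes were called on day 2, 61 higher and 47 lower, and DESeq2 called 196, 96 higher and 100 lower. Among those called with the block was the mesoderm gene Hand1 (adjusted p = 0.0233, and 0.147 without). Without a block, leaving out WT1 replicate 1 or 3, WT2 replicate 3, Reno m/m1 replicate 2 or 3, or Reno m/m2 replicate 1 gave 0, Reno m/m1 replicate 1 gave 7 and Reno m/m2 replicate 2 gave 19. Line m/m1 alone against WT gave 4, m/m2 alone 7, counts summed per line 7 and a coefficient for each line 23. Groups without overlap made up 1.46% of genes, where chance gives 0.433%.

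The day 2 shRNAs ask the same with acute depletion, of Reno or of Bahcc1. With the Bahcc1 shRNAs, Bahcc1 stood at 55.3 ± 28.3 CPM (n = 2) against 113 ± 10.4 (n = 2; -1.02 ± 0.34, adjusted p = 0.111). 2810410L24Rik stood at 0.188 CPM there, and at 0.0590 ± 0.0835 with the Reno shRNAs against 0.328 ± 0.182 CPM (2 and 18 counts, too few to test). With the Reno shRNAs, Bahcc1 was at 80.0 ± 7.69 CPM (-0.50, adjusted p = 0.412). The Bahcc1 shRNAs changed 224 of 14724 genes by edgeR, of which 194 rose and 30 fell. The long non-coding RNAs Kcnq1ot1 (248 ± 49.3 against 38.4 ± 7.5 CPM) and Snhg14 (43.6 ± 7.97 against 6.08 ± 1.40) rose, as did Cenpk, a kinetochore gene (11.5 ± 3.90 against 1.42 ± 0.171) and Top2a (440 ± 11.7 against 206 ± 15.8, adjusted p = 0.0495). Snai1, a factor of mesenchymal transition (7.01 ± 1.41 against 28.7 ± 0.815), the adhesion gene Zyx (139 ± 39.1 against 471 ± 44.2), Hdac7, Trim67 and the pluripotency factors Klf4 (24.3 ± 3.56 against 72.5 ± 16.3) and Klf5 (89.8 ± 1.08 against 262 ± 62.4) fell. Apart from Top2a, each of these had an adjusted p of 0.0479, just under the threshold.

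No list passed with the Bahcc1 shRNAs, with 0 by camera, 8 at an unadjusted p under 0.05, and 0 by fry. Wnt targets came closest, with a median of -0.80 and 1 of 12 members above 0 (camera, adjusted p = 0.0834). In the pluripotency list 2 of 28 members fell, Klf4 and Klf5, and 1 of 26 cell cycle genes, Top2a, rose (6 over the list alone). The count of 224 genes was 1695 without NT replicate 1, 2 without NT replicate 2, 0 without either Bahcc1 library and 0 with RLE scaling, 1618 without a filter, and 2874 by DESeq2, of which 1624 were higher. Leaving out NT replicate 1 or 2 or Bahcc1 replicate 1 or 2 gave 3, 8, 8 and 5 lists.

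With the Reno shRNAs edgeR called 0 of 14724 genes, 3343 had an unadjusted p under 0.05 and DESeq2 called 1934. Fibroblast genes were all below 0 (21 members, median -2.37, 1 over the list alone, camera adjusted p = 3.07e-05, and 0.632 with an estimated correlation). The smooth muscle and fibroblast genes Tagln (120 ± 15.6 against 456 ± 18.8 CPM, n = 2 each, adjusted p = 0.0722) and Acta2 (152 against 869 CPM, adjusted p = 0.0923) and the collagen gene Col4a1 (44.4 ± 0.0921 against 124 ± 29.0, adjusted p = 0.0657) fell short of the threshold. The mean log2(CPM + 1) of fibroblast genes was 6.61 and 3.38 in the NT replicates and 4.23 and 2.57 with the Reno shRNAs, and without NT replicate 1 the list median was 0.41 (adjusted p = 0.638). Surface ectoderm (-1.49), Hox and Cdx (-1.23), mesoderm (-1.15), BMP and TGF-beta (-0.99), Wnt targets (-0.84), Notch (-0.80) and endoderm genes (-0.77) were lower, with adjusted p of 0.000915 to 0.0271, and 0.328 to 0.632 with an estimated correlation. Over the list alone 3 endoderm, 2 mesoderm, 2 Notch, 2 BMP and TGF-beta and 1 surface ectoderm gene were lower. Cell cycle genes were higher (median 0.37, 11 of 26 over the list alone, adjusted p = 3.07e-05, and 0.328 with an estimated correlation). The surface ectoderm call ended without NT replicate 2 (adjusted p = 0.323) and the Hox call without NT replicate 1 or Reno replicate 2 (up to 0.794, with a median up to 0.29). Without Reno replicate 1 the endoderm and surface ectoderm medians were -1.35 and -0.97, and without Reno replicate 2 the endoderm median was -0.47. No filter gave 909 genes and a replicate block more.

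Set against each other, the Reno and Bahcc1 shRNAs differed in 0 genes by edgeR, with 713 at an unadjusted p under 0.05 and 34 by DESeq2. All 15 imprinted (median -0.56, adjusted p = 2.23e-05) and all 21 fibroblast genes (-1.34, adjusted p = 3.6e-05) were lower and cell cycle genes higher (0.14, adjusted p = 0.00959) with the Reno shRNAs, and none held with an estimated correlation (adjusted p = 0.639, 0.697 and 0.639). The fibroblast and cell cycle calls ended without Reno replicate 2 or Bahcc1 replicate 1 (adjusted p up to 0.289 and 0.276, with a fibroblast median up to 0.20). Without Reno replicate 1 their medians were -2.48 and 0.25, and without Bahcc1 replicate 2 the imprinted median was -0.23. Leaving out Reno replicate 1 or Bahcc1 replicate 2 gave 10 lists in place of 3. Log2 differences from the shared NT libraries correlated across genes at r = 0.696, against 0.477 in simulation, with a covariance of 0.474 against 0.158. With 2 NT libraries, the controls could not be split. Groups without overlap made up 53.5% of genes for Reno, 57.7% for Bahcc1 and 39.8% for their difference, where chance gives 33.3%.

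Gapmers tested loss of the Reno RNA without a change in the DNA. On day 2 the target was too low to show its depletion, at 0.196 ± 0.0950 CPM with Reno gapmers (n = 5) and 0.15 ± 0.0516 with scrambled gapmers (n = 2). Bahcc1 stood at 56.9 ± 6.96 against 62.9 ± 14.7 CPM (-0.14, adjusted p = 0.732). Of 13308 genes edgeR called 34, of which 32 rose and 2 fell. Of these 32, 15 code for ribosomal proteins, a group chosen after the result was seen. Rps29 rose from 213 ± 28.3 to 467 ± 95.4 CPM (1.13 ± 0.17), Rpl38 from 453 ± 79.6 to 828 ± 125, Rps28 from 716 ± 19.9 to 1292 ± 207, Rpl35 from 114 ± 2.38 to 204 ± 23.4 and Cox6c, a subunit of cytochrome c oxidase, from 20.8 ± 5.43 to 42.1 ± 4.65 (0.99 ± 0.15), each with an adjusted p of 0.0284. Amotl2, a regulator of Hippo signalling, fell from 84.8 ± 2.51 to 61.1 ± 1.95 CPM (-0.47 ± 0.08, adjusted p = 0.0389).

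With the gapmers, pluripotency genes were slightly higher (median 0.13, 21 of 28 above 0, 1 over the list alone, adjusted p = 0.0249) and progenitor (-0.17, 1 over the list alone, adjusted p = 0.0380) and Notch genes lower (-0.20, 1 over the list alone, adjusted p = 0.0281), and none held with an estimated correlation (adjusted p = 0.299, 0.689 and 0.462). The p53 targets Ccng1 (-0.10) and Zmat3 (-0.15) did not pass. The count of 34 was 2 without scrambled replicate 2, 72 without scrambled replicate 3, 22 and 7 without replicates 1 and 2 of gapmer 1, 0 for gapmer 2 alone, 99 without a filter and 290 by DESeq2. Leaving out scrambled replicate 2 or 3 left 1 list each (adjusted p up to 0.0978 for pluripotency and 0.234 for Notch), and the progenitor call also ended without replicate 2 of gapmer 2 (adjusted p up to 0.763, with medians from -0.29 without scrambled replicate 3 to 0.06 without scrambled replicate 2). Groups without overlap made up 18.7% of genes, where chance gives 9.52%.

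In the rescue set, Dox switched on 2810410L24Rik, which asks whether supplying Reno RNA undoes changes in Reno m/m2 cells. In Reno m/m2 cells it went from 0.215 ± 0.0271 CPM (n = 2) to 5.15 ± 2.25 CPM (n = 3) and in WT2 cells from 0.289 ± 0.0646 (n = 3) to 4.11 ± 1.58 CPM (n = 3). The log2 differences of 4.46 ± 0.73 and 3.83 ± 0.62 did not pass in edgeR (adjusted p = 0.621 and 0.516). In WT2 it was the only gene called by DESeq2 (adjusted p = 0.037). Bahcc1 stood at 88.5 ± 16.0 CPM with Dox and 81.1 ± 18.7 without in Reno m/m2, and at 98.5 ± 37.2 and 85.0 ± 38.3 in WT2. Without Dox, 3 of 13019 genes were higher in Reno m/m2 than in WT2. Rian, an imprinted lncRNA of the Dlk1-Dio3 locus, stood at 880 ± 117 against 56.7 ± 30.1 CPM (3.94 ± 0.47, adjusted p = 0.00801). A row that sums Meg3 of the same locus with other gene IDs stood at 550 ± 154 against 42.2 ± 6.63 CPM, and a row next to it, which also sums several gene IDs, at 102 ± 3.13 against 6.11 ± 1.61.

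Targets of p53 were higher in Reno m/m2 than in WT2 without Dox (15 of 17 above 0, 0 over the list alone, median 0.41, adjusted p = 1.18e-07, and 0.0265 with an estimated correlation), with Ccng1 at 422 ± 79.3 against 220 ± 187 CPM and Zmat3 at 297 ± 13.8 against 193 ± 39.2 (adjusted p = 0.998 for both). Y-linked (-2.62, 2 of 3 over the list alone), Hox and Cdx (-1.47), progenitor (-0.58) and BMP and TGF-beta genes (-0.49) were lower (adjusted p = 7.52e-06 to 0.0218, and 0.124 to 0.549 with an estimated correlation). WT2 replicate 3 without Dox had 2.69% of moderately expressed genes at 0 counts. Without it or Reno m/m2 replicate 2, the progenitor and Hox calls ended (adjusted p up to 0.954 and 0.908, with medians up to 0.03 and 0.58), and the BMP call ended without Reno m/m2 replicate 1 or WT2 replicate 2 (up to 0.306). Without WT2 replicate 1 the p53 and progenitor medians were 0.76 and -0.97, without Reno m/m2 replicate 1 the Hox median -2.99 and without WT2 replicate 3 the BMP median -0.28.

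Groups without overlap made up 11.5% of genes for the lines without Dox and 17.0% for Dox in Reno m/m2, where chance gives 20%, and 3.23% for Dox in WT2, where chance gives 10%. Dox called 0 genes by edgeR in Reno m/m2 (69 at an unadjusted p under 0.05, DESeq2 0), 0 in WT2 (111, DESeq2 1) and 0 for the difference between both effects (108, DESeq2 0). In Reno m/m2, pluripotency (median 0.28, adjusted p = 0.0012) and Hox and Cdx genes (0.81, adjusted p = 0.000415) were higher with Dox by camera, but not with an estimated correlation (adjusted p = 0.759 and 0.869). The first call ended without replicate 1 without Dox (adjusted p = 0.0960), the second without replicate 1 with Dox or replicate 2 without (up to 0.542), and without replicate 3 with Dox 5 lists passed. The pluripotency median was 0.17 without replicate 1 or 3 with Dox, and the Hox median 2.42 without replicate 1 without Dox and 1.26 without replicate 2 with Dox. In WT2, pluripotency (0.13), formative (0.17) and interferon genes (0.32) were higher (adjusted p = 0.0300 each, and 0.574 to 0.7 with an estimated correlation). None of the 3 passed when replicate 1 without Dox or replicate 3 with Dox was left out (adjusted p up to 0.901, 0.673 and 0.533). The formative and interferon calls also ended without replicate 3 without Dox, the former without replicate 1 with Dox and the latter without replicate 2 with Dox. Without replicate 2 without Dox the pluripotency and formative medians were 0.07 and 0.35, and without replicate 3 without Dox the pluripotency median was 0.31. The effect of Dox differed between the lines for formative (median -0.48) and Hox and Cdx genes (1.05, adjusted p = 0.0163 for both, and 0.704 and 0.809 with an estimated correlation). The formative call ended without replicate 1 with Dox of either line, Reno m/m2 replicate 1 without Dox, or WT2 replicate 3 with or without Dox (adjusted p up to 0.49). The Hox call ended without Reno m/m2 replicate 1 with Dox or 2 without, or WT2 replicate 2 with or 3 without Dox (up to 0.738, with a median down to -0.78), and its median was 1.59 to 2.46 without replicate 1 or 2 of WT2 without Dox, WT2 replicate 1 with Dox, or Reno m/m2 replicate 1 without or 2 with Dox.

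**Figure D3:**
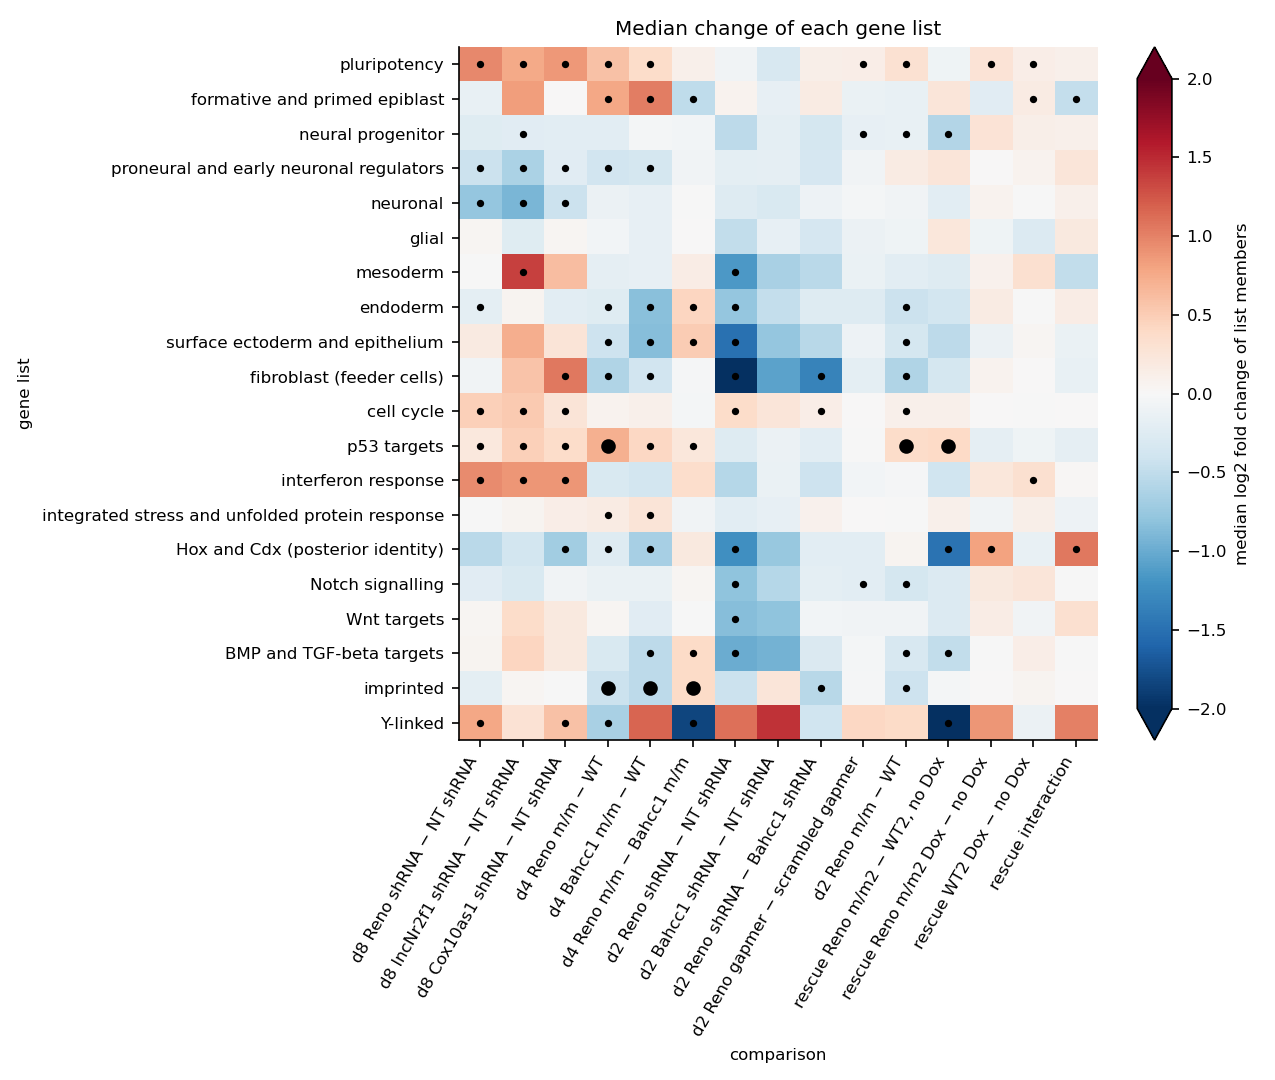
Median log2 difference of each of 20 gene lists (vertical) in 15 contrasts (horizontal), with the colour scale ending at -2 and 2. Small dots mark lists past the threshold with camera at an adjusted p under 0.05, large dots those that also pass with an estimated correlation.

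Across the experiments on Reno, log2 differences of shRNAs and mutants on day 2 correlated across genes at r = 0.416, gapmers and mutants on day 2 at 0.295, mutants on days 2 and 4 at 0.284 and the day 8 shRNAs with the day 2 mutants at 0.274. The day 4 mutants correlated at 0.0965 with the day 2 shRNAs and at -0.0289 with the gapmers. All 11 genes called in the day 4 mutants had the same sign in the day 2 mutants and the rescue lines without Dox. Of them, 9 had it in the day 8 shRNAs, 5 in the day 2 shRNAs and 2 with the gapmers. Lines were matched by label, which Y-linked genes did not always follow. Peg13 was called on both days. Of the 32 gapmer calls tested in both, all had the same sign in the day 2 mutants and 3 in the rescue lines. Glial genes passed in none of the 15 contrasts.

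ATAC-seq on day 2 asks whether the mutant cells open different regions. Its protocol text describes dorsal root ganglia while the titles name NPCs of day 2, so all values below hold only if the titles are right. Peaks numbered 26486 and 11906 in WT1, 20083 and 20512 in WT2, 28192 and 42284 in Reno m/m1, 6541 and 5049 in Reno m/m2, 15336 and 19371 in Bahcc1 m/m1, and 18510 and 18783 in Bahcc1 m/m2. Mean numbers were 20516.5 ± 17956 in Reno m/m (n = 4), 18000 ± 1812 in Bahcc1 m/m (n = 4) and 19746.75 ± 5989 in WT (n = 4), and neither difference from WT passed (two-sided exact permutation p = 0.857 and 0.600, where the smallest possible is 0.0286). The covered length was 6.57 Mb in Reno m/m, 5.23 Mb in Bahcc1 m/m and 6.17 Mb in WT (exact p = 0.857 and 0.429). Bahcc1 m/m peaks had a median width of 215.5 ± 6.86 bases against 238.75 ± 22.4 bases in WT (exact p = 0.0857).

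Of 62176 regions in Reno m/m and WT, 1261 were lost and 310 gained in Reno m/m. With 5049 strongest peaks from each library, the numbers were 317 and 265. A region on chromosome 1 from 121401240 to 121401674 (mm9) had a peak in 4 of 4 WT libraries and in 0 of 4 Reno m/m libraries (median fold enrichment 8.59), with equal peak numbers as well. A region on chromosome 10 from 10104022 to 10104428 had a peak in 3 of 4 Reno m/m libraries and no WT library (10.6). In Bahcc1 m/m, 716 of 49965 regions were lost and 380 gained, or 124 and 161 with equal numbers of peaks. The region on chromosome 4 from 13836486 to 13836807 had a peak in 4 of 4 Bahcc1 m/m libraries and 0 of 4 WT libraries (8.46), and in 3 of 4 with equal numbers.

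Shared peak positions gave a mean Jaccard index of 0.257 for libraries of 1 genotype against 0.219 for libraries of different genotypes among Reno m/m and WT (one-sided exact p = 0.114) and 0.322 against 0.309 for Bahcc1 m/m and WT (one-sided exact p = 0.0286). With equal numbers of peaks the difference went from 0.0381 to 0.0532 for Reno m/m (exact p = 0.0286) and from 0.0130 to 0.0145 for Bahcc1 m/m (exact p = 0.0571), which moves both across the threshold. Without Bahcc1 m/m1 replicate 2 the Bahcc1 difference was -0.00088, and it was 0.00241 and 0.00595 without the first replicates of m/m1 and m/m2. Lost regions in Reno m/m numbered 355 without WT1 replicate 1, 693 without WT1 replicate 2, 549 and 580 without WT2 replicates 1 and 2, and 2373 without Reno m/m1 replicate 2. Gained regions there numbered 19 and 20 without Reno m/m1 replicates 1 and 2, 151 and 170 without Reno m/m2 replicates 1 and 2, and 474, 469 and 511 without WT1 replicate 1 and WT2 replicates 1 and 2. In Bahcc1 m/m, lost regions numbered 143, 403, 252 and 251 without the 4 WT libraries in turn, and 1095 and 1179 without Bahcc1 m/m2 replicates 1 and 2. Gained regions there numbered 169, 111, 139 and 142 without the 4 Bahcc1 m/m libraries in turn, and 679, 626 and 751 without WT1 replicate 1 and WT2 replicates 1 and 2.

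**Figure D4:**
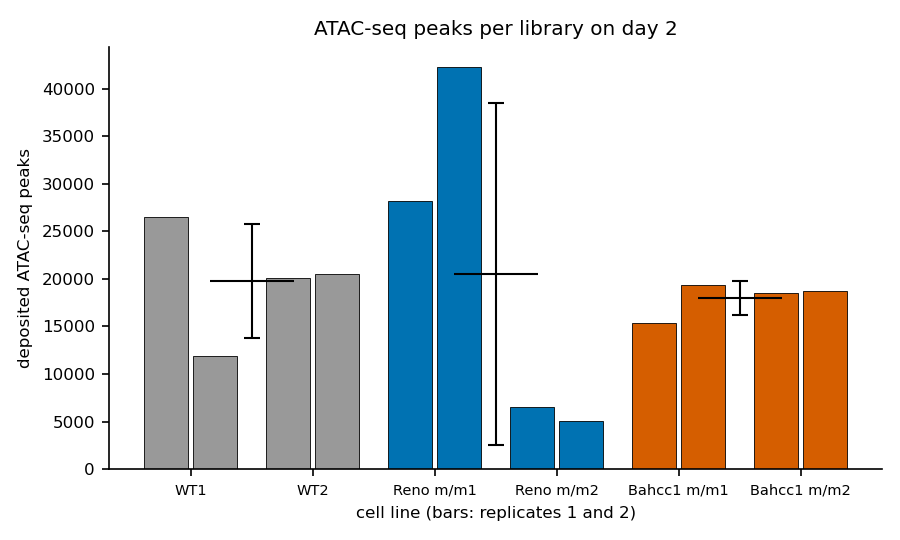
Number of ATAC-seq peaks per library on day 2, with bars for replicates 1 and 2 of each line and lines for the mean ± SD per genotype (n = 4 libraries).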

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

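Tests of the p53 list against each WT line and without low-complexity libraries were set before their results were seen. So were the gapmers' first length match and tests of each scrambled library. All other tests here, splits included, were chosen after. SEs of medians and their differences here are over genes, not libraries. Libraries far from the rest of their group were sought among 346 groups of values and found in 29, where chance gives about 1 in 20.

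Targets of p53 were higher in Reno m/m cells on days 2 and 4 and in Bahcc1 m/m cells on day 4 (for the last, adjusted p = 0.0711 with an estimated correlation). A WT line that stands apart is argued against for Reno m/m, since both Reno m/m lines together exceeded either WT line on either day by a median of at least 0.294 (SE 0.102), but not for Bahcc1 m/m, where m/m2 exceeded WT2 by 0.255 (SE 0.188). Low-complexity libraries are argued against for Reno m/m, whose day 4 median was 0.630 without them, and of 35 splits of the day 4 libraries 1 gave a p53 p-value as small for Reno m/m and 2 for Bahcc1 m/m. More dividing cells as the whole cause are argued against for Reno m/m. There the p53 median exceeded the cell cycle median by 0.258 on day 2 (SE 0.0836) and 0.648 on day 4 (SE 0.136). Less differentiated cells stay open, since it exceeded the pluripotency median by only 0.0572 (SE 0.122) and 0.131 (SE 0.169). With pluripotency scores as a covariate it was 0.253 on day 2 (adjusted p = 0.0805 with an estimated correlation) and 0.699 on day 4 (0.0184), where scores follow replicate number. Neither was tested for Bahcc1 m/m, and loss of the Reno RNA itself stays open, because the list moved by -0.0126 with the gapmers, whose target was too low to show its depletion, by -0.26 (SE 0.20) with the day 2 shRNAs and by -0.18 (SE 0.09) with Dox in Reno m/m2.

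Rian, Meg3 and a neighbouring row of the imprinted Dlk1-Dio3 locus were higher in Reno m/m2 than in WT2 in the rescue. If labels hold across sets, which the Y-linked genes of Reno m/m2 put in doubt, a difference of WT2 from WT1 fits this. On day 2 Reno m/m2 lay 0.318 above WT1 in the median of these 3, while WT1 lay 4.03 and Reno m/m2 4.43 above WT2. The same rows separated WT1 from WT2 and Bahcc1 m/m1 from m/m2 on day 4. Loss of Reno RNA as the whole cause is argued against, since Reno m/m1 lay at -0.0927 from WT1 and Dox moved the rows by -0.284, 0.111 and 0.0150 in Reno m/m2 (SE 0.351 to 0.443), where Rian lay 3.94 above WT2. An effect of the deletion that Reno RNA does not undo was not tested.

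With the Reno gapmers, ribosomal protein mRNAs were higher (median of 74 genes 0.418, 73 above 0), and 15 of the 32 genes called higher code for ribosomal proteins. A scrambled library that stands apart is argued against, with medians of 0.533 and 0.303 against each of them. Loss of Reno RNA stays open, since 2810410L24Rik fell past the threshold in no contrast. The median was -0.269 in the rescue lines, -0.0586 in day 4 Reno m/m and 0.365 in the day 2 mutants. It was 0.297 with the day 2 shRNAs and 0.316 with the day 8 shRNAs. Transcript length stays open, since shorter genes rose more (Spearman -0.323), as do RNA quality and other effects of the gapmers, which were not tested. The median exceeded that of 75 genes matched on length and expression (0.123) by 0.296 (SE 0.047), but these were longer (median 942 against 706.5 bases) and lower (log2 CPM 9.31 against 10.32), and it exceeded the 27 of them no longer than 706.5 bases by only 0.0328 (SE 0.0665).

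Splits of the libraries into groups of the same sizes test chance between libraries, not clonal lines. On day 4, 1 of 35 was as large for Reno m/m (11 genes, highest other 0) and for Bahcc1 m/m (314, highest other 4). Chance can be excluded there, though the 18 splits balanced by replicate number are too few. Chance between libraries can be excluded for the day 2 mutants, where 3 of 100 were as large (12). There the highest other split (336 genes) sets replicates 1 and 2 of both Reno m/m lines and WT2 against the rest. This points to a structure of the samples, and with a replicate block the count was 108. Of the 25 splits balanced by number, only the real one reached 12. For the day 8 shRNAs edgeR called 0 genes for each target (highest others 1, 5422 and 16), so all 35 of 35 splits are as large whatever the data, and nothing follows on chance. The split with 5422 genes sets the replicate 1 hairpin libraries and NT replicates 1 and 2 against the rest, which points to a structure of the samples. Chance cannot be excluded for Reno m/m against Bahcc1 m/m (1 gene, 2 of 35, highest other 606, which sets all replicate 1 against all replicate 2 libraries and points to a structure as well; with a replicate block the real count was 3). For WT2 with and without Dox the count of 0 makes all 10 splits as large in the same way (highest other 4496).

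For the number of lists past the threshold, chance cannot be excluded on day 8, on day 4 or in the day 2 mutants. As many lists were found in 13, 15 and 15 of 35 splits on day 8 (8, 8 and 9 lists, highest others 13, 14 and 12), in 5, 5 and 4 of 35 on day 4 (11, 11 and 7, highest others 13, 14 and 8) and in 11 of 100 for the day 2 mutants (10, highest other 14). For WT2 with Dox, 10 splits are too few (3 lists, 8 as large, highest other 8). For ATAC regions lost or gained, 10 of 35 splits were as large for Reno m/m (1571, highest other 4043). With equal numbers of strongest peaks it was 1 of 35 (582, highest other 563). For Bahcc1 m/m it was 1 of 35 (1096, highest other 1032). It was 2 with the stricter q value (1009, highest other 1042) and 5 with equal peaks (285, highest other 335). The settings disagree, so chance between libraries or lines can be excluded for neither mutant.

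The effects of both mutations differed in 1 gene and 7 lists on day 4, those of both shRNAs on day 2 in 3 lists, and those of Dox in both lines in 2 lists, each by a test of the difference. With an estimated correlation 1 of the 7 held, imprinted genes (adjusted p = 0.00747), and the others had adjusted p of 0.161 to 0.565 on day 4, 0.639 to 0.697 for the shRNAs and 0.704 and 0.809 for Dox. Between lines of 1 genotype, 3 genes differed between Bahcc1 m/m1 and m/m2 on day 4 (Rian and both rows beside it) and 5 between Reno m/m1 and m/m2 on day 2, among them the Y-linked Eif2s3y, Ddx3y, Uba1y and Uty.

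Single libraries lay far from the rest of their group as follows. On day 8, imprinted genes had a mean log2(CPM + 1) of 6.71 in Reno shRNA1 replicate 2 (next 6.26) and 6.33 in Cox10as1 shRNA2 replicate 2 (next 6.72), and Cox10as1 shRNA1 replicate 1 had the lowest share of absent genes (0.429%). On day 4, WT1 replicate 2 was highest in fibroblast genes (4.69), Tgfbi (39.7 CPM, next 20.3) and Nog (9.67 CPM, next 5.29). Reno m/m1 replicate 2 was highest in absent genes (1.72%) and Nog (2.72 CPM) and lowest in progenitor genes (4.50). Reno m/m1 replicate 1 was the only Reno m/m library with Y-linked reads (1.01, others 0), highest in Calcr (8.55 CPM) and lowest in Krt18 (114 CPM) and Krt19 (14.8 CPM). Reno m/m2 replicate 1 was lowest in Dlk1 (31.3 CPM) and highest in Col4a2 (136 CPM). Bahcc1 m/m2 replicate 2 was highest in absent genes (5.56%) and Xist (5.28 CPM) and lowest in p53 targets (5.2) and Bax (97.0 CPM), m/m2 replicate 1 highest in Rxrg (18.2 CPM) and m/m1 replicate 1 in Dppa2 (74.0 CPM). Among the gapmers, Reno gapmer 1 replicate 1 had 35.2 M counts (next 13.1) and its replicate 3 the lowest fibroblast score (2.06). Among the day 2 mutants, WT2 replicate 2 was lowest in p53 targets (5.21), WT2 replicate 1 highest in Zmat3 (249 CPM) and Hand1 (15.5 CPM), Reno m/m2 replicate 3 in Actg1 (6487 CPM), m/m1 replicate 1 in Cyp4f16 (10.8 CPM) and m/m2 replicate 2 in Sh3rf1 (19.1 CPM).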

How the results depend on the processing

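The alternatives were planned, except those named above as added after the data were seen. Among values of single genes, lists and regions under the alternatives, 1807 kept direction and side of the threshold, 394 no longer passed, 45 newly passed, 58 moved and 1 reversed. Among the counts and measures that answer a comparison, 332 were the same, 175 moved, 4 newly passed, 1 no longer passed and 1 reversed. Limits are the few libraries per group and, in the gapmer experiment, the low level of 2810410L24Rik. Where leaving out a library left 1 in an arm, it was assumed to vary like the other groups. The cause of the changes below was not tested.

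DESeq2 called 216, 136 and 4 genes for the day 8 Reno, lnc-Nr2f1 and Cox10as1 shRNAs, 113, 828 and 13 for day 4 Reno m/m, Bahcc1 m/m and their difference, 1934, 2874 and 34 for the day 2 shRNAs of Reno, Bahcc1 and their difference, 290 for gapmers, 196 for day 2 mutants and 1 for WT2 with Dox. Without a filter, edgeR called 17 for day 4 Reno m/m, 3 for the day 4 difference, 909, 1618 and 6 for the day 2 shRNAs and 99 for gapmers. With RLE factors the day 2 Bahcc1 shRNAs gave 0. With a replicate block, the counts were 61, 722 and 3 on day 4, 1851, 2631 and 5 for the day 2 shRNAs, 161 for gapmers and 108 for day 2 mutants. Besides calls given in the report, the block changed no other call of a named gene in the day 2 mutants, ended none of the 12 main calls and left 10 lists past the threshold, and it gave 7 genes between the Reno m/m lines and 20 in place of 4 between the WT lines. Libraries with the same number correlated after removal of group means at 0.379 to 0.597 for the day 2 shRNAs, 0.0482 to 0.442 on day 4, -0.462 to 0.743 on day 8, -0.0922 to 0.154 for gapmers and -0.513 to 0.454 in the rescue. Each line with its own coefficient gave 182 for Bahcc1 m/m, 0 for the day 4 difference and 23 for day 2 mutants. Lines alone gave 1 and 1 for day 4 Reno m/m, 5 and 133 for Bahcc1 m/m, 4 and 7 on day 2 and 0 for gapmer 2. Summed lines gave 40 for day 4 Reno m/m, 2 for the day 4 difference and 7 on day 2. Without both low-complexity libraries Bahcc1 m/m had 514 and the day 4 difference 0. Leaving out each library gave 1 to 12 for day 4 Reno m/m, 69 to 320 for Bahcc1 m/m, 0 to 6 for their difference, 0 to 90 and 0 to 1695 for the day 2 Reno and Bahcc1 shRNAs, 2 to 72 for gapmers and 0 to 19 for day 2 mutants. In the rescue lines without Dox it gave 2 to 4. A line alone was not run for the day 4 difference, where it has no meaning.

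Lists past the threshold with an estimated correlation numbered 0, 0 and 0 on day 8, 2, 1 and 1 on day 4, 0 and 0 for the day 2 Reno shRNAs and their difference from Bahcc1, 0 for gapmers, 1 for day 2 mutants, 1 for the rescue lines and 0, 0 and 0 for Dox in Reno m/m2, in WT2 and their difference. By fry they numbered, in the same order, 1, 0 and 0, then 2, 6 and 1, then 3 and 0, 0, 2, 1 and 0, 0 and 0. With a replicate block they numbered 6 for the day 2 Bahcc1 shRNAs, 7 for the shRNA difference and 4 for Dox in Reno m/m2, which also had 4 without the low-complexity library. Leaving out each library gave 6 to 10, 6 to 11 and 8 to 11 lists on day 8, 8 to 14, 9 to 13 and 5 to 10 on day 4, 9 to 11, 3 to 8 and 2 to 10 for the day 2 shRNAs, 1 to 3 for gapmers, 8 to 10 for day 2 mutants, 4 to 7 for the rescue lines, and 1 to 5, 0 to 4 and 0 to 3 for Dox.

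For the stages, TPM kept 3 of the 5 largest rises and 3 of the 5 largest falls, and a pseudocount of 0.1 kept 3 falls. TPM gave 452 genes 2-fold higher and 315 lower, a pseudocount of 0.1 gave 886 and 465, and a minimum of 10 CPM gave 2175 and 994. The cell cycle median of neurons over ES cells reversed from -0.0048 to 0.0889 with TPM. With WT libraries split between both day 4 mutants, r was 0.424 and the covariance 0.129. ATAC regions lost and gained in Reno m/m were 317 and 265 with equal peaks, 310 and 16 for 4 libraries against 0, and 355 to 2373 and 19 to 511 leaving out each library. In Bahcc1 m/m they were 124 and 161, 112 and 61, and 143 to 1179 and 111 to 751. With equal peaks the difference in similarity was 0.0532 for Reno m/m (exact p = 0.0286) and 0.0145 for Bahcc1 m/m (exact p = 0.0571). With all peaks, leaving out each library gave 0.0185 to 0.0589 for Reno m/m and -0.00088 to 0.0279 for Bahcc1 m/m, reversed without Bahcc1 m/m1 replicate 2. Leaving out each library, peak number differences from WT ranged from -6486 to 5926 and -4360 to 499.7, covered lengths from -1.97 to 2.03 and -1.82 to -0.176 Mb and widths from -18 to 2.58 and -31.5 to -14.2 bases, for Reno m/m and Bahcc1 m/m. A 50% overlap changed no region.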

Other observations

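All tests in this part were chosen after the results were seen, and the values below are given without an explanation. Y-linked genes divided the Reno m/m lines on day 2 and did not follow the line labels later. On day 2 their mean log2(CPM + 1) was 1.83, 1.73 and 1.87 in the 3 libraries of Reno m/m1 and 0.0296, 0.0216 and 0.0251 in those of Reno m/m2, while WT libraries lay between 0.690 and 1.42. On day 4, Reno m/m1 replicate 1 was at 1.01 and the other Reno m/m libraries, among them m/m1 replicate 2, at 0, while Bahcc1 m/m libraries lay between 0.679 and 1.24. In the rescue, Reno m/m2 libraries lay between 0.298 and 0.652 and WT2 libraries between 0.555 and 1.41. In the ATAC-seq data, 59 and 45 peaks lay on the Y chromosome in Reno m/m1, 4 and 5 in Reno m/m2 and 4 in WT1 replicate 2, the last 3 being the libraries with the fewest peaks, and 19 to 38 in the others.

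Replicate numbers divided the libraries of day 4 by pluripotency genes, whose mean log2(CPM + 1) was 5.18 to 6.51 in replicate 1 and 4.77 to 5.13 in replicate 2 of the 6 lines.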
